A study of Homo sapiens with 12 samples.

How the data were processed

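The series holds RNA sequencing of 12 samples of the HCC1954 cell line in 4 groups of 3 replicates, grouped by the sample titles. One table of read counts per gene was deposited. Per the file headers, the authors made these counts with featureCounts 1.4.6, counting fragments in paired-end mode against the GENCODE 25 annotation and summing exons by gene name. The command names 24 alignment files, of which the table holds 12 columns. It sets no strand option, no option to count reads that overlap several genes and no option for multi-mapping reads. Per the labels' protocols, the library kit was directional. Per the submitters' processing notes, FastQC 0.11.5, Trim Galore 0.4.5, STAR 2.4, SAMtools 1.2 and Subread 1.4.6 were used and the build was hg38 (GRCh38).

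The 12 count columns are named after alignment files. Each name was searched for in every label of every sample and of the series and was found in 0 of the 12 samples. Assigning columns by their order or by their values was not done, since either would put guessed treatments behind each result. The 12 columns of per-sample values were therefore not used; only their totals and ranges were looked at, to tell their unit. The tests fixed before the data were examined, which were quasi-likelihood fits, gene list tests and overlaps of calls, were not run, and neither were their alternatives.

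Used were the gene name, the exon coordinates and the exonic length of each of the 56269 rows, read with Python 3.11.15. Exons of a row were merged per chromosome and strand. In all rows, the merged exons summed to the length that the authors deposited, and the lists of chromosomes, starts, ends and strands had equal lengths. For each row, the exonic bases that lie also in an exon of another row were counted, on either strand, on the opposite strand and on the same strand. The reported limit was 10% of a gene's exonic bases, and 1 base and 50% were alternatives. These limits were chosen after the annotation columns were read. The overlap count was tested on simulated data, 60 random genes against a count base by base, and 0 were wrong. This describes the annotation: how many fragments fell on shared bases was not measured, and exons are annotated for transcripts that these cells need not express.

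Gene types were taken by name from GENCODE 29, also on GRCh38. Of 35914 rows on 1 chromosome and strand with a name that is unique in both, 33564 (93.5%) had the same start, end and strand in both releases, and 35279 (98.2%) overlapped. Coordinates are those of the deposited table, counted from 1. The 33 gene lists (863 different genes) and a panel of 28 genes were fixed before the data were examined. The rule for naming genes relied on fold changes and could not be applied. The genes named here are panel genes and list members chosen after their shared bases were seen, as the highest of a list, as members over 10%, or as contrasts to them.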

Results

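RNA was sequenced from 12 cultures of HCC1954, a human breast cancer cell line with amplification of ERBB2 (HER2). The labels give 4 groups with 3 biological replicates each: DMSO, a compound named only SNXB, lapatinib (an inhibitor of the EGFR and ERBB2 kinases), and a combination. Treatment lasted 24 hours, and each single agent was given at 1 µM. The doses within the combination and the target of SNXB are not given in the sources used here. The design implies comparisons of each treatment with DMSO and of the combination with each single agent.

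None of these comparisons was made, and no expression value is reported. The table holds 12 count columns, whose names match no label of the 12 samples or of the series, so no column could be given to a treatment. The count columns were not used, and the depth of each library and the error between replicates are not reported. What follows describes the genes that the table counts, from the gene names, exon coordinates and exonic lengths of its rows. These belong to the annotation and not to any sample, so they carry no replicate error and no test applies to them. Each percentage below is a share of annotated exonic bases or, beside a count of genes, a share of genes. None is a share of reads.

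Exons of different genes overlapped at many positions of the annotation. The counting command set neither a strand option nor an option to count reads that overlap several genes, and how reads on shared bases were assigned was not examined. Of the 18771 protein-coding genes that could be identified by name, 7781 (41.5%) had at least 1 exonic base that also lay in an exon of another feature. At least 10% of the exonic bases were shared in 3221 (17.2%), at least 50% in 547 (2.91%), and all of them in 80 (0.43%). Counting only overlaps with features on the opposite strand, 2089 genes reached 10%, and counting only overlaps on the same strand, 1222 did.

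ERBB2, the amplified receptor gene of this line and a target of lapatinib, lies on the plus strand of chromosome 17 at 39687914 to 39730426 (GRCh38). It shared 7.41% of its 10321 exonic bases, mostly 571 bases with MIEN1 on the opposite strand. EGFR, the other target of lapatinib, shared 1.49% of 12511 bases, all with EGFR-AS1 on the opposite strand. ERBB3, the kinase-impaired partner of ERBB2, shared 0.36%, and IGF1R, an insulin-like growth factor receptor, shared none. Of the 14 ERBB receptors and ligands, only NRG4 reached 10%, with 38.1% of its exonic bases lying opposite FBXO22.

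Of the 28 genes in the list of ERK pathway output, which lies downstream of these receptors, 4 shared at least 10%. DUSP6, a phosphatase that dephosphorylates ERK, lies on the minus strand of chromosome 12 at 89347232 to 89353271. It shared 1875 of its 4632 exonic bases (40.5%), all with a clone-named feature on the opposite strand. The early response gene IER3 shared 26.5%, PHLDA1 shared 16.5%, and CCND1, which encodes cyclin D1, shared 10.3%, again with features on the opposite strand. Under 10% were, among others, SPRY4, an inhibitor of receptor tyrosine kinase signalling, and MYC, both with no shared base, and the transcription factor gene ETV5 with 2.83%. Of the 25 FOXO target and PI3K feedback genes, PINK1 was over the limit with 39.4%, and IRS2 shared 1.41%. CDKN1B, TXNIP and BCL2L11 shared no base.

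In the integrated stress response list, 28 of the 33 members were found by name, and 6 of them shared at least 10%. These were DDIT4 with 41.2%, MTHFD2 with 33.2%, DDIT3 (CHOP) with 28.0%, SLC1A5 with 23.8%, ATF5 with 21.2% and CEBPB with 11.8%, each over the limit by overlaps on the opposite strand alone. The partner of DDIT3 was MARS, a methionyl-tRNA synthetase gene, over 355 of its 1266 exonic bases. ASNS, which encodes asparagine synthetase, shared none. Of the 30 heat shock genes, 3 reached 10%: HSPE1 with 23.9% (14.2% opposite HSPD1, which is in the same list), CRYAB with 20.6% and FKBP4 with 11.4%. DNAJB1 shared 6.21%, HSP90AA1 shared 3.75%, and HSPA8 shared 3.61%, part of it with the small nucleolar RNA gene SNORD14C on its own strand. HSPA1A and BAG3 shared none, but HSPA1A has a near-identical copy, HSPA1B, and how reads that fit both copies were counted was not examined.

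Cholesterol synthesis genes included 2 of the 9 listed genes with at least 50% of their exonic bases shared. CYP51A1, lanosterol demethylase, shared 82.2%, of which 78.8% of its bases lay in LRRD1 on the same strand. ACAT2 shared 52.3%, with SOD2 as its main partner on the opposite strand, and SOD2 in turn shared 2287 of its 18985 exonic bases. FDPS with 18.6%, IDI1 with 17.9% and HMGCS1 with 15.0% brought the list to 5 of 25 members over 10%. None of the 16 fatty acid synthesis genes reached that limit, and FASN, fatty acid synthase, shared no base.

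Among growth and housekeeping genes, the S phase list had 5 of 40 members over 10%, led by CCNE2 (cyclin E2) with 37.1% and TYMS (thymidylate synthase) with 26.2%. The G2 and mitosis list had 3 of 39, FOXM1 with 15.9%, PLK1 with 12.9% and BUB1B with 10.2%, while MKI67 shared none. Larger numbers were found among cytosolic ribosomal proteins, 15 of 62, with RPL10 highest at 55.5%, and among nuclear-encoded oxidative phosphorylation subunits, 12 of 39 found, with NDUFS7 highest at 49.1%. Of the ribosome biogenesis genes, 9 of 40 were over the limit, led by PPAN with 59.8%, mostly shared with the readthrough gene PPAN-P2RY11. Of the proteasome subunits, 7 of 31 were, led by PSMC1 with 75.8%, all opposite NRDE2. The iron storage gene FTH1 shared 62.4% and SRXN1, sulfiredoxin, 85.0%, both in the NRF2 target list. Across all lists, 833 of the 863 genes were found by name, and 485 of these shared no base. At least 10% was shared by 126 of them (15.1%), beside 17.2% of the protein-coding genes identified by name. The lists differ in size, and their counts were not compared by a test.

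The remaining lists are given by their counts over 10% among the members found by name. The antigen presentation list had 6 of 23, with PSMB10, an immunoproteasome subunit, highest at 34.8%. The interferon response list had 5 of 40, led by IRF9 with 48.4%. The lysosome list had 9 of 35, led by CTSD (cathepsin D) with 52.7%, and the NRF2 list had 5 of 25. The BCL2 family list had 3 of 16, led by BCL2L1 with 43.0%, opposite ABALON, and MCL1 shared 2 bases. The counts were 3 of 26 for ER chaperones, 3 of 28 for p53 targets, 3 of 26 for NF-kB targets, 2 of 21 for glycolysis, 2 of 22 for hypoxia and 1 of 21 for other receptor tyrosine kinases. HSPA5 and CDKN1A, in the ER chaperone and p53 lists, shared no base. Among markers, the counts were 3 of 20 for luminal, 1 of 21 for basal, 2 of 25 for squamous and 2 of 22 for mesenchymal genes, and VIM (vimentin) shared 24.4%. Markers of other cell types gave 3 of 12 for fibroblasts, 2 of 14 for blood cells, of which CD68 was highest at 85.8%, and 0 of 9 for endothelium. Of the 13 mitochondrially encoded mRNAs, 1 reached 10%, MT-ATP8, which overlaps MT-ATP6 on the same strand. None of the 15 histone genes did.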

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

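All alternatives were chosen after the annotation columns were read, and the planned ones were not run because the count columns were not used. No paired analysis was possible because no count column carries a replicate number. Of the 833 genes of the fixed lists, 126 shared at least 10% of their exonic bases. The number was 348 with any shared base, 9 at a limit of 50%, 34 with overlaps on the same strand only and 91 with overlaps on the opposite strand only. It was 123 with readthrough genes left out, and 129 when older symbols were also matched through the RefSeq gene table, which found 858 of the 863 genes. For protein-coding genes, 3221 shared at least 10%. The number was 7781 with any shared base, 547 at 50%, 2089 on the opposite strand only and 1222 on the same strand only. With readthrough genes left out, both as partners and from the genes counted, it was 2984. What a stranded count would have changed in the reads was not tested.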

Other observations

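The gene names of 28 rows had the form of a date, such as 1-Mar or 9-Sep, the form in which a spreadsheet program writes names such as MARCH1 or SEPT9. These rows carried 26 different names, since 1-Mar and 2-Mar each stood on 2 rows. Their positions tell them apart: the 1-Mar row on chromosome 4, with 10421 exonic bases, lies at MARCH1 of GENCODE 29, and the 1-Mar row on chromosome 1, with 9258 exonic bases, lies at MARC1. The 2-Mar row on chromosome 19 lies at MARCH2 and that on chromosome 1 at MARC2. A join by gene name loses these rows, among them genes of MARCH ubiquitin ligases, septins and mitochondrial amidoxime reductases. For the row named 15-Sep, on chromosome 1 at 86862445 to 86914424, no gene with a name of the forms searched for was found in GENCODE 29. These forms were MARCH, SEPT or DEC followed by a number, MARC1 and MARC2. A gene of another name at that position would have been missed, so the row was left unidentified.

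Because exons were summed by gene name, 178 rows combined exons from more than 1 chromosome, 44 of them from X and Y only. Y_RNA combined exons from 24 chromosomes, Metazoa_SRP from 23, and U3 and uc_338 from 18 each. A count on such a row belongs to a shared name and not to 1 locus.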
